A study of Mus musculus with 12 samples.

How the data were processed

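The measurements were made by chromatin immunoprecipitation followed by sequencing (ChIP-seq) of mouse CD4+ T cells. Per the labels, chromatin was digested with micrococcal nuclease, an enzyme that cuts between nucleosomes, to about 80% mononucleosomes and 20% dinucleosomes, and each immunoprecipitation gave about 100 ng of DNA. Antibodies against histone H3 trimethylated at lysine 4 (H3K4me3) or at lysine 27 (H3K27me3) were used, and the DNA was sequenced on an Illumina 1G Genome Analyzer. There were 6 cell types and 2 marks, which made 12 libraries with 1 library per cell type and mark. No input or other control library was analysed here.

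The deposited files list 1 aligned read per line with chromosome, start, end, a class (U0, U1 or U2), a score and a strand. The score in the deposited files was 0 on every line and was not used. Reads were 25 bp long, except for 1223036 reads of 24 bp in the nTreg H3K4me3 library. The classes U0, U1 and U2 were read as 0, 1 and 2 mismatches to the genome, which is the usual meaning of these codes and is not defined in the labels. Reads at positions already seen were present in the deposited files. The aligner and the genome build are not given in the sources used here. The highest read coordinates lay beyond the end of the last gene of the GRCm38 gene table by 1777885 bp on chromosome 1 and by 2798245 bp on chromosome 8. Gene coordinates of that build were therefore not used, no coordinate was converted, and regions are given by chromosome and position as the reads carry them, counted from 1. Gene names, gene lists, and the exon or intron context of a region were not analysed here.

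From these reads the following was computed. For each library, 1 read was kept per chromosome, strand and 5′ end, and its 5′ end was moved 75 bp downstream, towards the centre of the nucleosome. Libraries of the same mark were thinned at random to the smallest of the 6, which left 1891922 reads for H3K4me3 and 6540287 reads for H3K27me3. Bins of 1 kb were called enriched when the count passed an upper Poisson tail of 1e-06 over the mean density. The density was taken over 2512.668 Mb, the summed length of the 4-kb bins that held a read in any library. This required 9 reads per bin for H3K4me3 and 14 reads for H3K27me3. Enriched bins were merged into islands over gaps of up to 1 bin for H3K4me3 and up to 3 bins for H3K27me3.

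The H3K4me3 islands of the 6 libraries were joined, and the summit of each joined island was the 200-bp bin with the most pooled reads. A site was the summit with 2 kb on either side. This gave 18317 sites, of which 17805 lay on autosomes, 506 on X and 6 on Y. Sites took the place of gene promoters in each result planned for promoters. A site was marked in a library when its window held at least 15 reads for H3K4me3 or 30 reads for H3K27me3 in the thinned library, which is the count that passes the same Poisson tail.

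For comparisons, all distinct reads of each window were counted and divided by a size factor, the median ratio of a library to the geometric mean over sites marked in all 6 libraries of that mark. Results of that division are called normalised reads. Ratios between 2 libraries carry a 95% interval from the exact conditional binomial method (Clopper-Pearson). A site was called higher or lower when the ratio was at least 2 in either direction, the interval excluded 1 and the site was marked in at least 1 of the 2 libraries. The intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. With 1 library per cell type and mark, a difference compares libraries and not conditions, has no replicate check, and no p-value is given. Where a library held no read at a site, the fold was computed against a floor of 3 counts in that library and is written as a lower limit.

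Comparisons were Th1, Th2, Th17, iTreg and nTreg each against naive cells, and iTreg against nTreg. Regions were named by rule: for each comparison and mark, the 5 sites with the highest and the 5 sites with the lowest ratio by the interval bound nearest to 1 among sites marked in at least 1 of the 2 libraries, leaving out a site that overlapped one already taken. Sites that stood apart in 1 cell type were ranked by the smallest bound of the 5 ratios against the other cell types, with each bound above 2. The relation between the changes of the 2 marks was described by Spearman's rho across sites marked by either mark in either cell type, with an offset of 0.5 reads and an interval from 200 bootstrap draws over sites. Neighbouring sites are not independent, so that interval describes these sites only. Counts for independent changes of the marks are products of the shares called for each mark among sites that could be called for both, that is, sites marked by each mark in at least 1 of the compared libraries. The ranks of the other mark at sites that stood apart in 1 cell type were compared with the ranks at all sites that met the marking rule for that list, and again at those of them where the other mark was marked in any cell type. Both of these comparisons were chosen after the data were seen.

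The calculation was tested on simulated data. Counts were drawn for the real sites from the real libraries' means, with 50 sites changed by each fold size. In the Th1 against naive simulation of H3K4me3 (14239 sites), 54% of 2-fold changes and 96% of 3-fold changes were called. In the nTreg against naive simulation of H3K4me3 (13481 sites), 48% of 2-fold and 90% of 3-fold changes were called. The corresponding shares for H3K27me3 were 60% and 98% for Th1 (4466 sites) and 50% and 98% for nTreg (4703 sites). A change of exactly 2-fold meets the required ratio in only part of the draws at any depth. Unchanged sites gave 110, 86, 11 and 16 calls in these simulations, in the same order. These draws hold counting error only, so the calls may understate variation inside a library. Parts of the same H3K4me3 library, compared below, differed at 3.28% of sites in naive and 7.37% in nTreg cells. These shares include an effect of removing repeated positions over the whole library. The interval contained the true ratio in 96.25% of 20000 simulated pairs of Poisson counts.

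The groups, the comparisons, the marking rule, the scaling, the thresholds and the first set of alternatives were fixed before the data were examined. These alternatives were reads at repeated positions kept, a Poisson tail of 1e-09, no thinning, windows of 1 kb on either side of the summit for H3K4me3 and 5 kb for H3K27me3, scaling by the total of distinct reads (called read-total scaling), no requirement of marking, and the correlation over all sites. Windows were planned around annotated start sites and were placed around summits once the gene table was set aside. Perfect-match reads only, autosomes only, background subtraction, thinning of each compared pair, and read-total scaling of counts beyond those of the comparisons were added after the data were seen. The placing of sites by summit, the ranking of sites that stood apart in 1 cell type, the counts shared by all comparisons, the random split of the naive reads, the comparison of parts of a library and the description of the sex chromosomes and of the longest H3K27me3 regions were also chosen after the data were seen. Sites were the same under every alternative. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.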

Results

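H3K4me3, a mark of active and primed promoters, and H3K27me3, a mark of Polycomb repression, were compared among naive CD4+ T cells, the helper types Th1, Th2 and Th17, induced regulatory T cells (iTreg) and natural regulatory T cells (nTreg) of the mouse. The H3K4me3 libraries held between 2033339 reads in Th17 cells and 6635158 reads in iTreg cells. The H3K27me3 libraries held between 10599323 reads in iTreg cells and 16028716 reads in nTreg cells. Reads at positions already seen made up 45.1% of the naive, 34.3% of the iTreg and 59.2% of the nTreg H3K27me3 reads, against 9.94% in Th1, 15.8% in Th2 and 14.0% in Th17 cells. For H3K4me3 this share was highest in iTreg cells at 23.4% and lay between 6.74% and 9.87% in the other cell types. Distinct reads ranged from 1892057 to 5085161 for H3K4me3 and from 6540326 to 11110478 for H3K27me3.

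Sites were placed by H3K4me3 islands alone, so the lower number of sites with H3K27me3 follows from that rule and does not compare the marks. H3K27me3 formed more long islands than H3K4me3. At equal depth, H3K4me3 islands numbered between 12517 in naive and 13818 in Th1 cells, and covered between 21.1 Mb in naive and 33.4 Mb in iTreg cells. H3K27me3 islands covered 50.001 Mb in naive, 35.5 Mb in Th1, 46.5 Mb in Th2, 47.9 Mb in Th17, 55.9 Mb in iTreg and 76.1 Mb in nTreg cells. Each of these 6 lengths moved by more than 1.5 times with repeated reads kept, to between 69.5 Mb in Th1 and 185.9 Mb in nTreg cells, and with a stricter tail, to between 16.2 Mb in Th1 and 41.1 Mb in nTreg cells. Naive cells came above iTreg cells with repeated reads kept, at 119.6 against 112.3 Mb. The median island length was 1 to 2 kb for both marks, and islands of 10 kb or more numbered 19 to 97 for H3K4me3 and 717 to 1775 for H3K27me3, for which wider gaps were merged. Of the 18317 sites, 9454 (51.6%) carried H3K4me3 in all 6 cell types and 2588 in 1 cell type. H3K27me3 marked 2537 sites (13.9%) in all 6 cell types and none of the cell types at 12595 sites (68.8%). Per cell type, H3K4me3 marked 11638 sites in naive, 13204 in Th1, 12969 in Th2, 12519 in Th17, 12815 in iTreg and 12153 in nTreg cells. H3K27me3 marked 3980 sites in naive, 3306 in Th1, 4003 in Th2, 3994 in Th17, 3879 in iTreg and 4419 in nTreg cells.

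Sites that carried both marks in the same cell type were least frequent in naive cells, at 1656 sites, and most frequent in Th2 cells, at 2544 sites. Th1 cells had 1843 such sites, Th17 cells 2284, iTreg cells 1996 and nTreg cells 2278. Independent placement of the marks over the sites would have given 2529 in naive, 2383 in Th1 and 2834 in Th2 cells. It would have given 2730 in Th17, 2714 in iTreg and 2932 in nTreg cells. The marks met less often than that in each cell type. The sites were chosen by H3K4me3 and leave out places without its islands, so this holds among the sites and does not describe the genome. Of the sites with H3K27me3, 41.6% also carried H3K4me3 in naive cells, against 55.7% in Th1, 63.6% in Th2, 57.2% in Th17, 51.5% in iTreg and 51.6% in nTreg cells. The naive H3K4me3 library also had the lowest enrichment over background, 20.0-fold against 28.3-fold to 80.5-fold in the others. A fixed read threshold does not correct for this, so library and cell type cannot be told apart for these counts and shares. Enrichment was highest in iTreg cells, which did not have the most sites with both marks. Both marks were present in all 6 cell types at 476 sites. With perfect-match reads alone the counts of sites with both marks fell to 556 in naive, 562 in Th1, 967 in Th2, 732 in Th17, 1023 in iTreg and 369 in nTreg cells, so their order among cell types depended on this setting.

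The H3K4me3 libraries differed in how far sites stood above background, from 20.0-fold in naive and 28.3-fold in nTreg to 57.3-fold in Th2 and 80.5-fold in iTreg cells, with 30.3-fold in Th17 and 49.2-fold in Th1 cells. For H3K27me3 this enrichment was 8.86-fold in naive, 6.98-fold in Th1, 10.4-fold in Th2, 11.6-fold in Th17, 9.97-fold in iTreg and 13.4-fold in nTreg cells. Scaling by the total of distinct reads instead of by shared sites moved every H3K4me3 ratio to naive by a log2 of 0.74 in Th1, 0.90 in Th2, 0.40 in Th17, 1.05 in iTreg and 0.29 in nTreg cells. For H3K27me3 the shift was -0.27 in Th1, 0.24 in Th2, 0.41 in Th17, 0.23 in iTreg and 0.65 in nTreg cells. Changes are therefore given relative to sites that were marked in all 6 cell types, and splits into higher and lower sites are set beside their values under read-total scaling.

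Some deposited files consisted of consecutive parts in which the mismatch classes started anew, which allowed a look at variation inside a library. Parts of the naive H3K4me3 library differed at 3.28% of marked sites and parts of the nTreg H3K4me3 library at 7.37%. At the read number of the naive part, Th1 differed from it at 22.1% and nTreg at 16.0% of sites. At the read number of the nTreg part, naive cells differed from it at 13.6% of sites. For H3K27me3, parts of the same library differed at 4.11% of sites in naive, 2.77% in Th1, 1.77% in Th2 and 1.97% in Th17 cells. Repeated positions were removed over the whole library, so a later part lacks positions already seen in an earlier part. In the naive H3K27me3 library, part 2 kept 1508004 of its 3464042 reads. The differences between parts include this effect and are not a clean measure of variation inside a library. Such parts share their cells and immunoprecipitation and do not replace replicates. Both iTreg libraries and the nTreg H3K27me3 library were not ordered by mismatch class, so the way their files were prepared and the cell type cannot be told apart.

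Between Th1 and naive cells, H3K4me3 was higher in Th1 cells at 1475 sites and lower at 1678 of 14239 sites. The ratio was at least 4 at 469 of the higher sites and at 537 of the lower sites, and at 1113 and 251 sites under read-total scaling. The highest site lay at 6:129641501-129645500, with 413 normalised reads in Th1 and 1.42 in naive cells, a 292-fold difference (95% interval 52.1 to 11545) that rested on 1 naive read. At 13:19829301-19833300, naive cells had no read and Th1 cells were at least 48.4-fold higher. A pair of high sites lay close together on chromosome 9. At 9:123969901-123973900 Th1 cells were 101-fold higher (34.3 to 491), on 3 naive reads, and at 9:123949701-123953700 they were 70.7-fold higher (27.4 to 261), while H3K27me3 at the latter was 2.85-fold lower in Th1 cells (1.61 to 5.19).

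Among the sites that lost H3K4me3 in Th1 cells, 11:52123101-52127100 fell from 1299 normalised reads in naive to 40.2 in Th1 cells, 32.3-fold (23.7 to 45.2). H3K27me3 at that site rose from 14.8 to 173 normalised reads, 11.7-fold (6.18 to 24.8). At 11:115277101-115281100, H3K4me3 was 93.8-fold lower in Th1 cells (31.6 to 459), on 3 Th1 reads, and H3K27me3 was 13.4-fold higher (4.34 to 67.0), on 3 naive reads. At 2:59283501-59287500 H3K4me3 was 56.3-fold lower (18.8 to 277), on 3 Th1 reads, and H3K27me3 9.86-fold higher (3.13 to 49.9), on 3 naive reads. The loss at 9:85504701-85508700, from 133 to 0.956 normalised reads (1 Th1 read), came without a change of H3K27me3 beyond counting error, which was 1.77-fold higher (0.404 to 10.6), on 3 naive reads.

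H3K27me3 was higher in Th1 than in naive cells at 392 sites and lower at 784 of 4466 sites. At 16:44882901-44886900 Th1 cells had 137 normalised reads against 1.48 in naive cells, 92.5-fold more (16.3 to 3684), on 1 naive read, and H3K4me3 was 6.73-fold lower (3.46 to 14.3). At 4:149410701-149414700 H3K27me3 was 21.9-fold higher in Th1 cells (10.4 to 55.1) while H3K4me3 was 2.45-fold lower (1.97 to 3.06). The site that lost most H3K27me3, 4:46619901-46623900, went from 133 normalised reads in naive to 7.86 in Th1 cells, 17.0-fold lower (7.90 to 43.4), and its H3K4me3 rose 5.10-fold (3.68 to 7.21). At 15:76057501-76061500 H3K27me3 was 15.1-fold lower (6.99 to 38.7) and H3K4me3 5.50-fold higher (3.08 to 10.7). Higher sites made up 46.8% of the changed H3K4me3 sites in Th1 cells, 88.3% under read-total scaling and 50.6% with windows of 1 kb on either side. For H3K27me3 the share was 33.3%, and 21.8% under read-total scaling, but it rose to 56.4% with windows of 5 kb on either side and to 60.8% without the requirement that a site be marked.

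In Th2 cells H3K4me3 was higher than in naive cells at 1205 sites and lower at 2087 of 14160 sites. A difference of at least 4-fold was reached at 330 higher and 914 lower sites, and at 1106 and 417 under read-total scaling. The highest site, 1:40372901-40376900, had 313 normalised reads in Th2 and 4.25 in naive cells, 73.6-fold more (24.97 to 358), on 3 naive reads, and no more than 10.9 in any other cell type. H3K27me3 at this site was 3.06-fold lower in Th2 cells (1.63 to 5.87). At 9:123949701-123953700 H3K4me3 was 63.1-fold higher (24.5 to 233), close to its level in Th1 cells, with 358 normalised reads in Th2 and 401 in Th1 cells. At 11:31266901-31270900 H3K4me3 was 60.8-fold higher (20.6 to 297), on 3 naive reads, and H3K27me3 3.25-fold lower (2.06 to 5.22).

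The site at 11:52123101-52127100 lost H3K4me3 in Th2 cells even more than in Th1 cells, with 23.4 normalised reads and a 55.5-fold difference from naive cells (37.6 to 85.4), and its H3K27me3 was 11.1-fold higher (5.92 to 23.5). Th17 cells kept 678, nTreg cells 432 and iTreg cells 310.4 normalised H3K4me3 reads there. At 18:56592701-56596700 H3K4me3 was 44.5-fold lower in Th2 cells (25.2 to 87.1), and the other cell types ranged from 201 to 482 normalised reads. At 15:60008301-60012300 no H3K4me3 read was found in Th2 cells, which were at least 54.5-fold lower than naive cells.

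H3K27me3 was higher in Th2 than in naive cells at 584 sites and lower at 947 of 4802 sites. At 8:75247901-75251900 H3K27me3 rose from 7.41 normalised reads in naive to 190.0 in Th2 cells, 25.7-fold (10.8 to 79.7), as H3K4me3 fell from 926 to 77.5, 12.0-fold (9.54 to 15.2). At 6:125446301-125450300 H3K27me3 was 37.4-fold higher (10.2 to 312), on 2 naive reads, and H3K4me3 10.8-fold lower (5.12 to 26.3). At 3:87609901-87613900 H3K27me3 was 38.4-fold higher (10.5 to 320.2), on 2 naive reads, while H3K4me3 differed by less than its counting interval, 0.798-fold (0.614 to 1.04). At 17:28804301-28808300 H3K27me3 was 15.4-fold lower in Th2 cells (8.41 to 30.8) and H3K4me3 5.04-fold higher (2.88 to 9.52). The share of higher sites among those changed in Th2 cells was 36.6% for H3K4me3 and 38.1% for H3K27me3. Under read-total scaling these shares were 86.6% and 54.1%, and windows of 5 kb on either side gave 51.3% for H3K27me3.

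In Th17 cells H3K4me3 was higher than in naive cells at 1280 sites and lower at 1466 of 13682 sites, of which 300 and 409 reached 4-fold, against 549 and 246 under read-total scaling. At 3:37421701-37425700 Th17 cells had 473 normalised H3K4me3 reads against 8.50 in naive cells, 55.6-fold more (25.3 to 153), and no other cell type exceeded 11.7. At 1:60836901-60840900 H3K4me3 was 52.7-fold higher in Th17 than in naive cells (17.6 to 259), on 3 naive reads, and iTreg cells were higher still, with 681 normalised reads against 224 in Th17 cells. At 7:140206301-140210300 H3K4me3 was 54.3-fold higher (14.6 to 455), on 2 naive reads, and H3K27me3 3.95-fold lower (1.64 to 10.1). The site 11:115277101-115281100, low in Th1 cells, was also 80.5-fold lower in Th17 than in naive cells (22.0 to 669.7), on 2 Th17 reads. At 5:144528901-144532900 Th17 cells had no H3K4me3 read and were at least 25.4-fold lower.

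H3K27me3 was higher in Th17 than in naive cells at 415 sites and lower at 917 of 4682 sites. At 6:99229301-99233300 H3K27me3 rose from 2.96 to 171 normalised reads, 57.6-fold (15.8 to 478), on 2 naive reads, and H3K4me3 fell from 450.4 to 31.7, 14.2-fold (8.93 to 23.9). At 8:75247901-75251900 H3K27me3 was 36.6-fold higher (15.6 to 113) and H3K4me3 10.1-fold lower (7.65 to 13.5). At 2:164146301-164150300 H3K27me3 was 14.3-fold lower (7.71 to 28.8) and H3K4me3 7.55-fold higher (2.92 to 24.8). At 2:32427501-32431500 H3K27me3 was 22.6-fold lower (12.2 to 46.6), and it was 11.4-fold lower in Th1 cells (6.38 to 22.0). Higher sites made up 46.6% of changed H3K4me3 sites and 31.2% of changed H3K27me3 sites in Th17 cells. Read-total scaling gave 77.3% and 58.7%, and windows of 1 kb on either side gave 52.1% for H3K4me3.

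Against naive cells, iTreg cells had the most changed H3K4me3 sites, with 1702 higher and 2473 lower of 13973 sites. Of these, 464 and 919 reached 4-fold, against 1902 and 355 under read-total scaling. At 1:60836901-60840900 iTreg cells had 681 normalised reads against 4.25 in naive cells, 160.3-fold more (54.8 to 778), on 3 naive reads, while nTreg cells had 25.5 and Th17 cells 224. At 17:8072901-8076900 H3K4me3 was 156-fold higher in iTreg cells (27.9 to 6186), on 1 naive read, and H3K27me3 was 4.11-fold lower (1.90 to 9.84). At 3:103218101-103222100 H3K4me3 was 149-fold lower in iTreg cells (39.9 to 1248), on 2 iTreg reads. At 11:63805301-63809300 H3K4me3 was 49.1-fold lower (32.7 to 77.0), from 486 normalised reads in naive to 9.88 in iTreg cells. The sites X:99683101-99687100, 251-fold lower (68.1 to 2091) on 2 iTreg reads, and Y:345701-349700, at least 31.9-fold higher, lay on sex chromosomes, on which iTreg cells had fewer X and more Y reads in both libraries.

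H3K27me3 changed at fewer sites in iTreg cells, with 239 higher and 554 lower than in naive cells of 4441 sites. Of the 114 sites on X in this comparison, 49 were lower and 2 higher. The autosomal site with the strongest loss, 11:76659301-76663300, had 176 normalised H3K27me3 reads in naive and 8.41 in iTreg cells, 20.95-fold fewer (9.86 to 53.2), and its H3K4me3 was 3.53-fold higher (2.74 to 4.62). At 5:124290301-124294300 H3K27me3 was 20.0-fold higher in iTreg cells (6.59 to 99.3), on 3 naive reads, and H3K4me3 2.48-fold lower (2.03 to 3.03). At 4:147525701-147529700 H3K27me3 was 13.0-fold higher (5.34 to 41.1) and H3K4me3 5.15-fold lower (2.60 to 10.4). The share of higher sites was 40.8% for H3K4me3 and 30.1% for H3K27me3 in iTreg cells, and 88.8% and 51.4% under read-total scaling.

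nTreg cells had the fewest changed H3K4me3 sites against naive cells, with 932 higher and 1464 lower of 13481 sites. Of these, 214 and 345 reached 4-fold, against 358 and 220 under read-total scaling. At 16:89719901-89723900 nTreg cells had 207 normalised H3K4me3 reads against 14.2 in naive cells, 14.6-fold more (7.77 to 31.1), and the next highest cell type was iTreg with 39.5. At 12:110837701-110841700 H3K4me3 was 22.3-fold higher (5.86 to 189), on 2 naive reads, and H3K27me3 2.46-fold lower (1.13 to 5.55). At 2:155464701-155468700 H3K4me3 was 9.31-fold higher in nTreg cells (4.52 to 22.2) while H3K27me3 stayed high, with 203 normalised reads in naive and 187 in nTreg cells. The site 11:63805301-63809300, which lost H3K4me3 in iTreg cells, was also 66.8-fold lower in nTreg than in naive cells (30.4 to 183). At 2:49667301-49671300 H3K4me3 was 28.3-fold lower in nTreg cells (10.7 to 106) and low in Th2 and iTreg cells, with 3.60 and 7.91 normalised reads, but present in Th1 and Th17 cells, with 177 and 237.

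H3K27me3 was higher in nTreg than in naive cells at 212 sites and lower at 488 of 4703 sites. At 11:98855901-98859900 H3K27me3 was 9.47-fold higher in nTreg cells (5.41 to 18.1) and H3K4me3 fell from 334 to 55.8 normalised reads, 5.99-fold (4.35 to 8.41). Th1 and Th2 cells resembled nTreg cells at this site, with 193 and 192 normalised H3K27me3 reads. At 5:139632701-139636700 H3K27me3 was 14.8-fold higher (4.86 to 73.6), on 3 naive reads, reaching 65.9 normalised reads in nTreg cells against at most 9.80 elsewhere. At 9:42848701-42852700 H3K27me3 was 18.9-fold lower in nTreg cells (10.2 to 38.8). At 12:33538101-33542100 it was 19.1-fold lower (6.06 to 97.0), on 3 nTreg reads. In nTreg cells 38.9% of changed H3K4me3 sites and 30.3% of changed H3K27me3 sites were higher, and read-total scaling turned these to 62.2% and 85.6%. With repeated reads kept, which concerns 59.2% of the nTreg H3K27me3 reads, 404 sites were higher and 767 lower.

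Between the regulatory T cell types, H3K4me3 was higher in iTreg than in nTreg cells at 2009 sites and lower at 2548 of 14398 sites. These included 615 higher and 1142 lower sites with a difference of at least 4-fold, against 1518 and 749 under read-total scaling. At 3:142183501-142187500 iTreg cells had 322 normalised reads against 2.42 in nTreg cells, 133-fold more (36.7 to 1099), on 2 nTreg reads, and Th17 cells came next with 20.1. At 1:60836901-60840900 iTreg cells were 26.8-fold higher than nTreg cells (17.4 to 43.3). At 7:75468701-75472700 nTreg cells had no H3K4me3 read and iTreg cells were at least 24.5-fold higher. Among the sites lower in iTreg cells, 15:87370101-87374100 had no iTreg read and was at least 54.2-fold lower. Its H3K27me3 was also 2.83-fold lower in iTreg cells (1.77 to 4.71). At 12:110724501-110728500 H3K4me3 was 187-fold lower (32.3 to 7508), on 1 iTreg read, and H3K27me3 2.28-fold lower (1.72 to 3.05).

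H3K27me3 was higher in iTreg than in nTreg cells at 573 sites and lower at 574 of 4783 sites. At 5:64765501-64769500 it was 93.2-fold higher (16.2 to 3729), on 1 nTreg read, and H3K4me3 was 5.33-fold lower (3.12 to 9.33). At 5:124293101-124297100 iTreg cells had 114 normalised H3K27me3 reads, 29.9-fold more than nTreg cells (11.3 to 112), and no other cell type exceeded 14.6. At 11:98855901-98859900 H3K27me3 was 18.96-fold lower in iTreg cells (9.43 to 44.6) and H3K4me3 4.60-fold higher (3.41 to 6.35). At 9:44470101-44474100 H3K27me3 was 29.0-fold lower (7.74 to 244), on 2 iTreg reads, and H3K4me3 3.29-fold higher (1.77 to 6.78). A 6.96-fold lower H3K27me3 signal at 17:39449301-39453300 (6.14 to 7.92) came from a window with more H3K27me3 reads than any other named site. It held 329 normalised reads in iTreg and 2293 in nTreg cells. H3K4me3 in that window was also lowest in iTreg cells, with 40.7 normalised reads against 92.1 to 312 in the other cell types. Without an input library, reads that gather there without either mark cannot be told apart from the marks. Higher sites made up 44.1% of changed H3K4me3 and 49.96% of changed H3K27me3 sites between iTreg and nTreg cells, and 80.9% and 20.2% under read-total scaling. Other alternatives turned the H3K27me3 share the other way, to 75.9% without the requirement of marking, 59.5% with windows of 5 kb on either side and 52.3% with repeated reads kept.

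**Figure D1:**
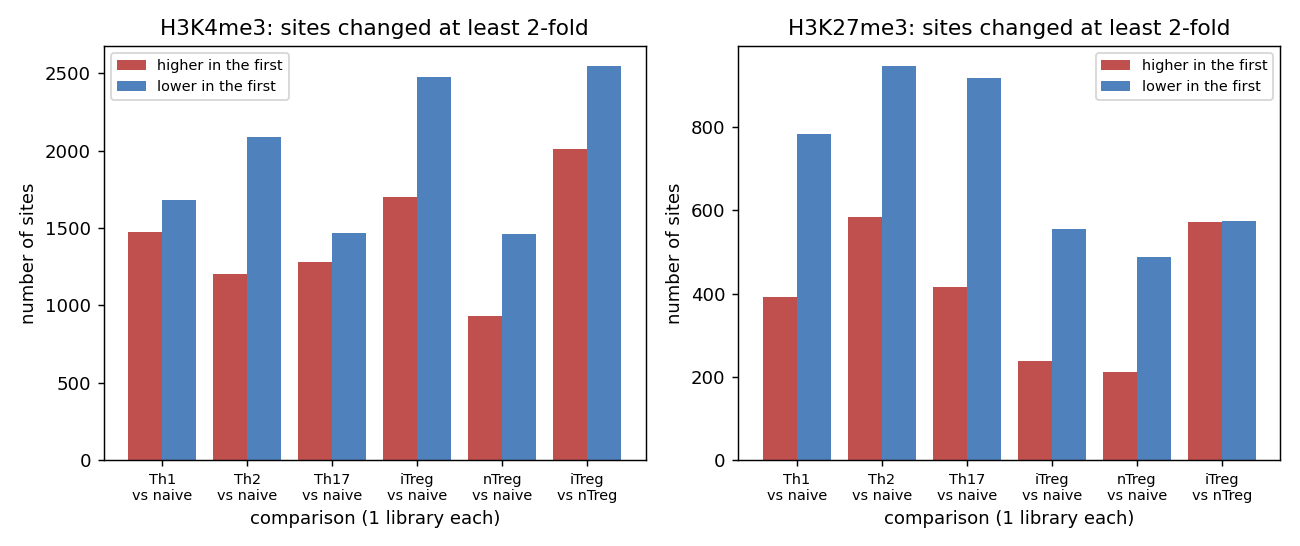
Number of sites (vertical axes) called higher or lower in each comparison (horizontal axes) for H3K4me3 and H3K27me3, with 1 library per cell type and mark. Against naive cells, changed H3K4me3 sites were most frequent in iTreg cells (1702 higher, 2473 lower) and least frequent in nTreg cells (932 higher, 1464 lower).

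With perfect-match reads alone, the share of higher sites among changed H3K4me3 sites crossed the middle in Th1 cells at 56.6%, in Th17 cells at 53.0%, in iTreg cells at 52.7% and between iTreg and nTreg cells at 63.5%. It was 49.8% in Th2 and 30.3% in nTreg cells. Random reads of the same number gave 57.6% in Th1, 53.7% in Th17, 52.9% in iTreg cells and 54.0% between iTreg and nTreg cells, and 49.3% in Th2 and 40.1% in nTreg cells. The share thus crossed the middle in the same 4 comparisons without a restriction to perfect matches. In nTreg cells, and between iTreg and nTreg cells, the share still differed between perfect-match and random reads. Read-total scaling raises every ratio of these comparisons by a constant, so its higher shares follow from that shift and give no direction of change.

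Across all pairs of cell types, the helper types resembled each other most. H3K4me3 differed at 10.6% of sites between Th1 and Th17, 11.9% between Th2 and Th17 and 13.2% between Th1 and Th2 cells. Naive and nTreg cells differed at 17.8% of sites, naive and Th17 cells at 20.1%, naive and Th1 cells at 22.1%, naive and Th2 cells at 23.2%, and naive and iTreg cells at 29.9%. The share was highest between iTreg and nTreg cells, at 31.7%. For H3K27me3 the helper types again differed least, at 11.4% between Th1 and Th2, 11.9% between Th2 and Th17 and 12.4% between Th1 and Th17 cells. Naive cells differed from nTreg cells at 14.9%, from iTreg cells at 17.9%, from Th1 cells at 26.3%, from Th17 cells at 28.4% and from Th2 cells at 31.9% of sites. iTreg and nTreg cells differed at 23.98%. Under read-total scaling the helper types still differed least for H3K4me3, at 12.5% to 16.3%, and naive and iTreg cells most, at 55.7%, above iTreg and nTreg cells at 48.1%. For H3K27me3, Th2 and Th17 cells then differed least, at 12.2%, followed by naive and iTreg cells at 17.5%, with Th1 and Th2 cells at 20.1% and Th1 and Th17 cells at 24.8%. These shares depend on the depth of both libraries, which differed between pairs. For H3K4me3 the shares against naive cells rose in the same order as enrichment over background, from 28.3-fold in nTreg to 80.5-fold in iTreg cells. The strength of the immunoprecipitation and a difference between cell types therefore cannot be told apart for these shares.

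Sites at which H3K4me3 stood above each of the other 5 cell types numbered 106 in iTreg, 86 in naive, 66 in Th1, 41 in Th2, 39 in nTreg and 23 in Th17 cells. Sites with H3K4me3 below each of the others numbered 29 in nTreg, 26 in iTreg, 21 in Th2, 7 in naive, 2 in Th1 and 0 in Th17 cells. Under read-total scaling the sites above the others numbered 262 in iTreg, 90 in Th1, 68 in Th2, 26 in naive, 18 in nTreg and 18 in Th17 cells, and those below numbered 35 in nTreg, 20 in naive, 11 in Th2, 6 in iTreg, 1 in Th1 and 0 in Th17 cells. In Th1 cells the leading sites lay close together at 6:129641501-129645500 and 6:129586901-129590900, with 413 and 349 normalised reads. In Th2 cells 11:53458101-53462100 and 11:53174901-53178900 followed 1:40372901-40376900, with 319.8 and 196 normalised reads against at most 13.3 in the other types. The third Th1 site, 5:100807901-100811900, had 242 normalised H3K4me3 reads in Th1 cells. Its H3K27me3 was 10.1 normalised reads in Th1 and 12.1 in Th2 cells, against 48.7 to 228 in the other cell types. Th2 cells had 17.1 normalised H3K4me3 reads there, so the low H3K27me3 was not particular to Th1 cells. The leading nTreg site, 12:119680701-119684700, combined the highest H3K4me3, 167 normalised reads, with the lowest H3K27me3, 24.8 against 61.8 to 148 elsewhere.

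H3K27me3 stood above each of the other cell types at 31 sites in Th1, 19 in Th2, 9 in naive, 5 in Th17, 4 in iTreg and 2 in nTreg cells, and under read-total scaling at 8 in Th1, 29 in Th2, 3 in naive, 11 in Th17, 4 in iTreg and 20 in nTreg cells. In Th1 cells, 13 of the 31 sites also had the lowest H3K4me3 of the 6 cell types, against 3.96 at the rate of all sites that carried H3K27me3 in Th1 cells. At 4:148696501-148700500 Th1 cells had 155 normalised H3K27me3 reads against at most 11.3 elsewhere, and 17.2 normalised H3K4me3 reads against 48.6 to 234 elsewhere. In Th2 cells, 9 of the 19 sites had the lowest H3K4me3, against 2.76 at that rate, and in naive cells 6 of 9, against 0.972. Read-total scaling gave 6 of 8 in Th1, against 0.779, 9 of 29 in Th2, against 2.13, and 3 of 3 in naive cells, against 0.895. The remaining lists gave 1 of 5 in Th17, 0 of 4 in iTreg and 1 of 2 in nTreg cells, against 0.220, 1.91 and 0.318. Under read-total scaling they gave 1 of 11, 0 of 4 and 4 of 20, against 1.00, 1.00 and 4.66, with no excess.

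At sites picked by H3K4me3 the H3K27me3 ranks often compared background, so they are also given for the sites where H3K27me3 was marked in any cell type. Of the sites with the highest H3K4me3, 13 of 41 in Th2, 8 of 23 in Th17, 11 of 66 in Th1 and 15 of 86 in naive cells had the lowest H3K27me3, against 3.26, 1.99, 3.06 and 8.53 at the rate of all sites with H3K4me3 in that type, whereas 20 of 106 in iTreg cells compared with 21.4 and 7 of 39 in nTreg cells with 18.8. Where H3K27me3 was marked in any type, the counts were 7 of 15 in Th2, 6 of 11 in Th17, 7 of 20 in Th1, 8 of 35 in naive, 7 of 31 in iTreg and 1 of 19 in nTreg cells, against 2.26, 1.90, 2.28, 4.82, 5.82 and 4.32. Under read-total scaling they were 12 of 27 in Th2, 4 of 8 in Th17, 14 of 24 in Th1, 4 of 14 in naive, 30 of 78 in iTreg and 1 of 6 in nTreg cells, against 3.004, 0.497, 9.72, 2.88, 12.0 and 0.515. Of the sites with the lowest H3K4me3, 9 of 21 in Th2 cells had the highest H3K27me3, against 3.56, but H3K27me3 was marked in any type at 5 of the 21, of which 2 were highest, against 0.928. In iTreg cells both ranks exceeded their rates. Of 26 such sites, 9 had the lowest H3K27me3, against 5.53, and 5 the highest, against 2.45. Of the 11 where H3K27me3 was marked in any type, 7 had the lowest, against 2.46, and 2 the highest, against 1.75. In nTreg cells 20 of 29 had the lowest H3K27me3, against 15.1, and 0 the highest, against 1.03. Of the 6 where H3K27me3 was marked in any type, 2 had the lowest, against 1.59, and 0 the highest, against 0.838. Under read-total scaling the sites where H3K27me3 was marked in any type fell to 3 in Th2 and 1 in iTreg cells, and of 11 in nTreg cells 2 had the lowest and 7 the highest H3K27me3, against 1.11 and 4.04.

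**Figure D2:**
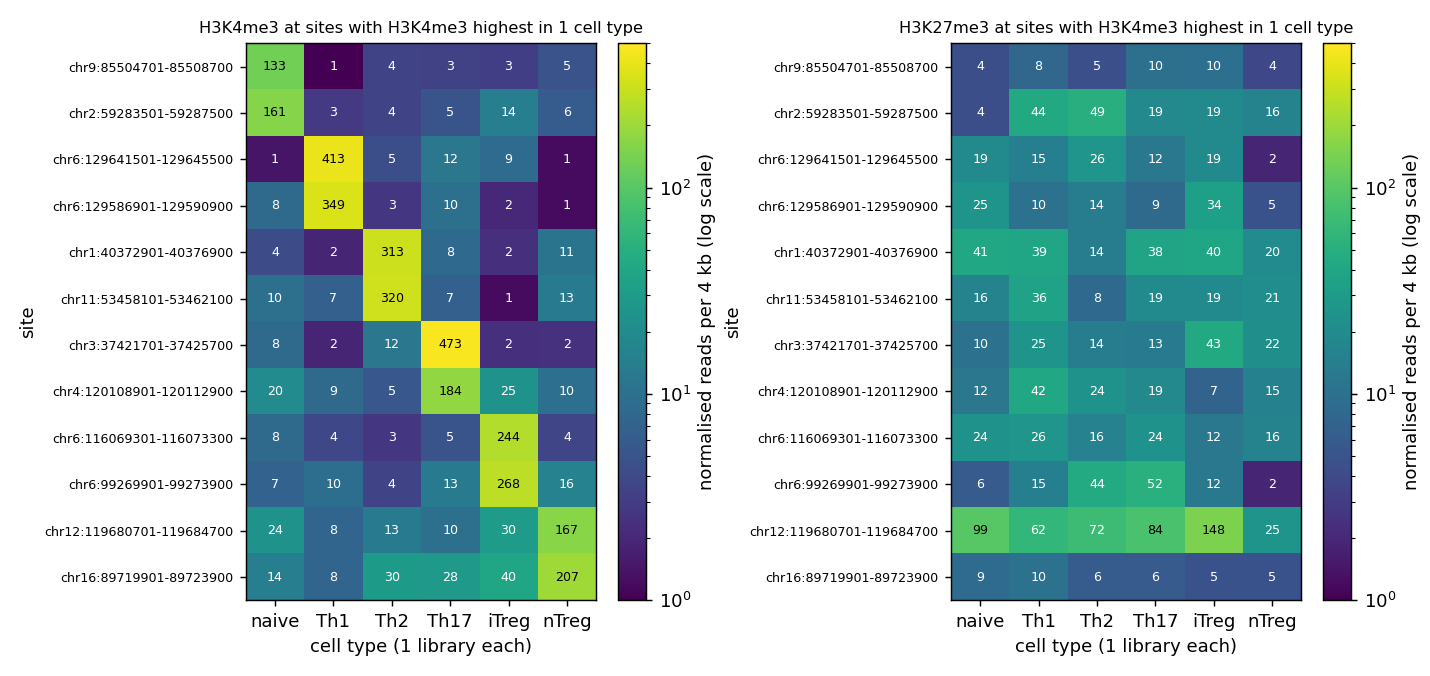
Normalised reads per 4 kb (colour, log scale) of H3K4me3 and H3K27me3 in the 6 cell types (horizontal axes, 1 library each) at the leading sites (vertical axes) with H3K4me3 highest in 1 cell type. The Th1 site 6:129641501-129645500 had 413 normalised H3K4me3 reads and the Th17 site 3:37421701-37425700 had 473.

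Loss of H3K4me3 relative to naive cells was shared by all 5 other cell types at 490 sites, and gain at 55 sites. H3K27me3 was lower than in naive cells in all 5 types at 95 sites and higher at 11 sites. The balance turned for H3K4me3 under read-total scaling, with 172 sites lower and 293 higher, and H3K27me3 was then lower at 37 sites and higher at 22. At 9:85504701-85508700 H3K4me3 had 133 normalised reads in naive cells and between 0.956 and 4.85 in the others. At 8:73735901-73739900 H3K4me3 had 12.7 normalised reads in naive cells and between 63.0 in nTreg and 195 in Th2 cells. At 10:94841501-94845500 H3K27me3 had 99.2 normalised reads in naive and at most 24.8 in the other cell types, and H3K4me3 rose from 14.2 in naive cells to 275 in iTreg and 210.3 in Th1 cells. At 11:75008501-75012500 H3K27me3 had 13.3 normalised reads in naive cells and between 69.7 and 143 in the others. All 5 comparisons used the same naive library, so part of these counts may come from that shared control. In 20 simulations of unchanged libraries, the mean count was 0.55 (highest 3) for lower and 4.1 (highest 9) for higher H3K4me3, and 0.1 (highest 1) and 1.5 (highest 4) for lower and higher H3K27me3. Independent calls would have given 0.239 and 0.0463 sites for H3K4me3 and 0.172 and 0.00449 sites for H3K27me3. The simulations cover counting error only, so a property of the naive library would not show in them.

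Opposite changes of the 2 marks were set against independent changes among the sites where both marks could be called, between 2724 sites for iTreg and 3448 for Th2 cells. Against naive cells they were more frequent in each comparison except for gain of H3K4me3 with loss of H3K27me3 in nTreg cells. In Th1 cells 151 sites gained H3K4me3 and lost H3K27me3, against 64.1 for independent changes, and 138 sites lost H3K4me3 and gained H3K27me3, against 63.0. In Th2 cells the counts were 169 against 95.9 and 194 against 93.4. In Th17 cells they were 149 against 99.7 and 110 against 43.4. In iTreg cells they were 103 against 38.2 and 61 against 50.3, and in nTreg cells 42 against 63.9 and 63 against 30.7. Changes in the same direction were rarer than independent changes would give. Both marks rose at 7 sites in Th1 cells (35.8 for independent changes), 13 in Th2 (65.6), 12 in Th17 (43.4), 10 in iTreg (15.0) and 9 in nTreg cells (29.1). Both fell at 47 sites in Th1 (113), 106 in Th2 (137), 47 in Th17 (99.7), 72 in iTreg (128) and 19 in nTreg cells (67.5). Under read-total scaling the counts for gain of H3K4me3 with loss of H3K27me3 and for the reverse were 373 against 238 and 62 against 18.8 in Th1, 291 against 203 and 129 against 57.9 in Th2, 159 against 101 and 85 against 38.3 in Th17, 183 against 100 and 26 against 23.9 in iTreg, and 35 against 36.7 and 114 against 99.6 in nTreg cells. Changes in the same direction were again rarer, though both marks rose at 82 sites in iTreg cells against 89.0, except that both rose at 217 sites in nTreg cells, against 198.

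Over all sites with either mark the relation was weak. Spearman's rho between the changes was -0.0921 in Th1 (-0.110 to -0.0781), -0.158 in Th2 (-0.174 to -0.145), -0.146 in Th17 (-0.162 to -0.129), -0.0793 in iTreg (-0.0925 to -0.0592) and -0.0229 in nTreg cells (-0.0378 to -0.00717), each against naive cells. It was positive between iTreg and nTreg cells, at 0.233 (0.216 to 0.248), where the joint changes followed no single direction. At the 3325 sites where both marks could be called, 165 sites were lower in iTreg cells for both marks against 149 for independent changes, and 48 were higher for both against 46.9. H3K4me3 was higher and H3K27me3 lower at 69 sites against 47.5, and the reverse held at 90 sites against 147. Read-total scaling gave 273 lower for both marks against 194, 64 higher for both against 65.4, 229 with H3K4me3 higher and H3K27me3 lower against 256, and 14 of the reverse against 49.5. With repeated reads kept, rho against naive cells was -0.0309 in Th1, -0.1165 in Th2, -0.0938 in Th17, -0.0438 in iTreg and -0.0475 in nTreg cells, each outside the interval given. The rho is taken across sites, which are not independent replicates. At most sites H3K27me3 was not marked and its ratio reflected background, and over all sites the nTreg value changed sign to 0.0017.

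Sites with both marks in naive cells kept both least often in Th1 cells. At the depth of 1 of a pair of equal random parts of the naive reads, 1116 sites carried both marks, and 72.3% (69.6 to 74.9) carried both in the other part. Of these sites, 46.0% (43.0 to 48.9) carried both marks in Th1 cells, 58.0% in Th2, 59.0% in Th17, 61.4% in iTreg and 55.9% in nTreg cells at the same depth. H3K4me3 alone remained at 35.7% of them in Th1, 25.5% in Th2, 23.7% in Th17, 19.6% in iTreg and 11.8% in nTreg cells, against 10.2% in the other naive part. H3K27me3 alone remained at 30.6% in nTreg cells, 13.2% in Th1, 12.9% in Th2, 14.7% in Th17 and 15.1% in iTreg cells, against 16.6% in the other naive part. Th1 cells also had the lowest H3K27me3 enrichment over background, 6.98-fold, and lost H3K27me3 most often at sites with H3K27me3 alone in naive cells. Of those, 11.2% had H3K4me3 alone and 21.4% neither mark in Th1 cells, against 0.507% and 4.90% in the other naive part. The ranges in the other cell types were 1.56% to 7.82% and 3.09% to 12.6%. Resolution of sites with both marks therefore cannot be told apart from weaker H3K27me3 calling across the Th1 library. Conversely, of 2365 sites with H3K27me3 alone in naive cells, 37.6% carried both marks in Th2, 29.6% in nTreg, 28.2% in Th17, 23.5% in iTreg and 21.5% in Th1 cells, against 8.37% in the other naive part. The naive H3K4me3 library had the lowest enrichment over background, 20.0-fold against 28.3-fold to 80.5-fold in the others, which a fixed read threshold does not correct for.

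**Figure D3:**
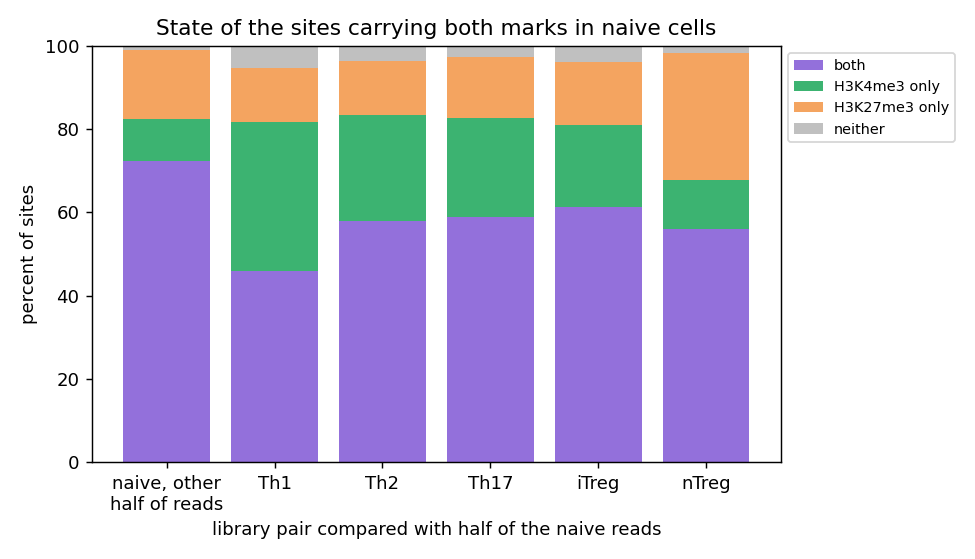
Percent of the sites with both marks in a random part of the naive reads (vertical axis) that carried both marks, H3K4me3 alone, H3K27me3 alone or neither in the library pairs on the horizontal axis, at equal depth. Both marks were found at 72.3% of them in the other naive part and at 46.0% in Th1 cells.

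H3K27me3 regions present in all 6 cell types numbered 3087, and the longest, 15:102735001-102864000, spanned 129 kb. Its H3K27me3 density was 3.78 RPKM (reads per kb per 1000000 distinct reads) in naive, 3.97 in Th1, 4.10 in Th2, 4.95 in Th17, 5.52 in iTreg and 4.23 in nTreg cells. H3K4me3 there was low, between 0.334 in iTreg and 0.816 RPKM in nTreg cells. Regions of 69 kb at 2:74447001-74516000 and 68 kb at 6:52138001-52206000 followed. A region of 64 kb at 11:3035001-3099000 was high in the libraries of both marks. H3K27me3 reads had 5.86 to 6.79 RPKM in 5 cell types and 2.61 in iTreg cells. H3K4me3 reads had 9.82 RPKM in naive, 3.84 in iTreg and 5.23 to 5.72 in the other cell types. No input library was analysed, so reads that gather in this region without either mark cannot be told apart from the marks.

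Reads on X and Y set the iTreg and nTreg libraries apart from the others for both marks. The labels give no sex of the animals, so sex and cell type cannot be told apart here. Away from sites, the density of H3K27me3 reads on X relative to autosomes was 1.60 in Th1, 1.44 in Th2, 1.33 in Th17 and 1.17 in naive cells, but 0.594 in iTreg and 0.619 in nTreg cells. For H3K4me3 it was 0.725 in Th1, 0.646 in Th2, 0.821 in Th17, 0.716 in naive, 0.540 in iTreg and 0.349 in nTreg cells. H3K27me3 islands on X numbered 2006 in Th1, 1289 in Th2, 1055 in Th17 and 526 in naive cells, against 235 in iTreg and 265 in nTreg cells. Per 1000000 perfect-match reads, the H3K4me3 reads on Y numbered 425 in iTreg and 162 in nTreg cells, against 37.1 in naive, 24.8 in Th1, 19.2 in Th2 and 25.5 in Th17 cells. For H3K27me3 they were 204 in iTreg and 74.3 in nTreg cells, against 27.1 in naive, 25.1 in Th1, 16.2 in Th2 and 19.4 in Th17 cells. The H3K4me3 site at X:99683101-99687100 had between 154 and 198 normalised reads in naive, Th1, Th2 and Th17 cells, 0.791 in iTreg cells on 2 reads and 1.21 in nTreg cells on 1 read. At the 6 sites on Y, comparisons with iTreg or nTreg cells include this difference in Y reads.

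**Figure D4:**
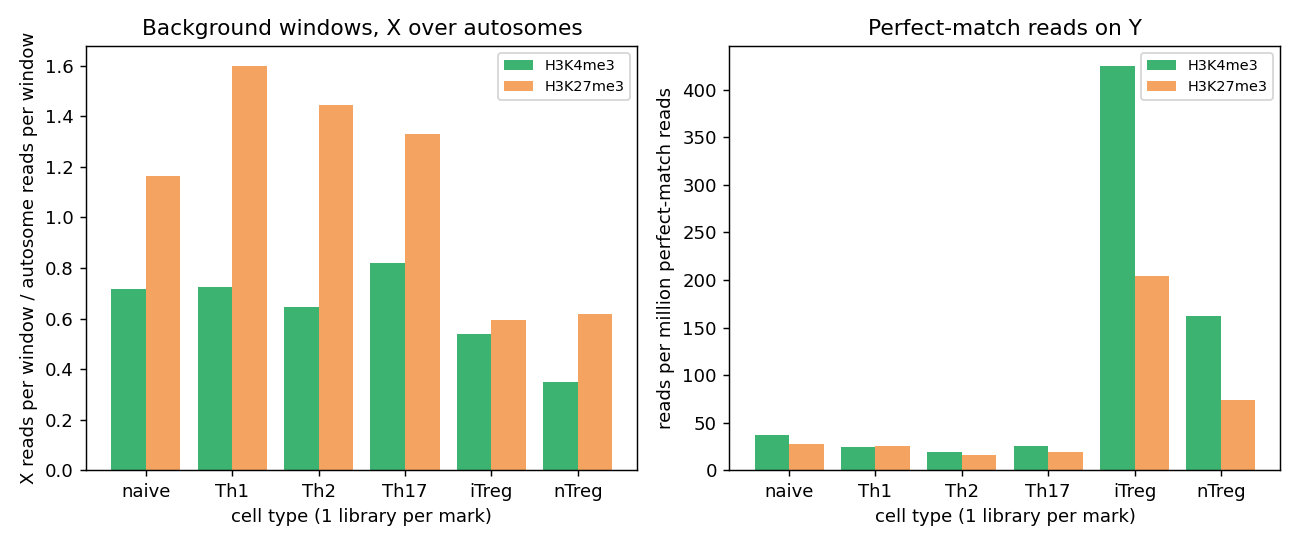
Density of background reads on X relative to autosomes, and reads on Y per 1000000 perfect-match reads (vertical axes), by cell type (horizontal axes) and mark, 1 library each. The iTreg and nTreg libraries had the fewest X reads (0.594 and 0.619 for H3K27me3) and the most Y reads (425 and 162 for H3K4me3).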

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

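Tests of mismatched placement on Y, of male cells in the naive sample, of the strength of the naive immunoprecipitation, of scaling and of reads with mismatches were chosen only after the result was seen. The tests of male cells in the regulatory samples, of duplicate removal and of fewer reads in the perfect-match setting were set before theirs was seen.

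Apart from 6 sites, the Y chromosome was outside the comparisons of cell types, and reads on it stood out in the iTreg and nTreg libraries. Reads on Y per 1000000 perfect-match reads were 425 in iTreg and 162 in nTreg cells for H3K4me3, and 204 in iTreg and 74.3 in nTreg cells for H3K27me3. The highest value of the other cell types was 37.1 for H3K4me3 and 27.1 for H3K27me3, both in naive cells.

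More Y reads in the iTreg and nTreg libraries went with fewer X reads. Reads placed on Y through mismatches alone would have left no excess of perfect-match reads, but the smallest ratio to naive cells, that of nTreg H3K27me3, was 2.74 (2.22 to 3.41). Cells of male animals in the iTreg and nTreg samples may explain the pattern, since in 74.1% of the 27 bins of 100 kb on Y that held perfect-match reads, iTreg and nTreg cells both lay above the other 4 cell types, with the marks pooled. The share of male cells was not estimated for these samples, and iTreg cells had more Y reads than nTreg cells but also more X reads for H3K4me3. The labels used here give no sex of animals, so a difference in sex and a difference between cell types stay open for sites on X and Y. If the animals differed, autosomal comparisons of iTreg or nTreg cells with the other 4 cell types would carry that difference too. It cannot be told apart from cell type there.

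H3K27me3 on X was lower in naive cells than in Th1, Th2 and Th17 cells. Cells of male animals in the naive sample as the whole cause would need 34.9% male cells and 39.1 Y reads per 1000000 perfect-match reads, taking nTreg cells as the male level, but naive cells had 27.1 (22.4 to 32.5). Removal of duplicate reads as the whole cause is argued against by all naive reads, of which 6.10% (6.08 to 6.11) lay on X, below the lowest of the other 3 at 7.21%. A weaker immunoprecipitation of the naive library cannot be told apart from a difference between cells, because enrichment over background was 8.86 in naive cells and lower in Th1 cells alone, at 6.98. A biological difference between naive and helper cells stays open and was not tested.

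More H3K4me3 sites were lower than higher against naive cells in all 5 comparisons at the settings of the report. With windows of 1 kb on either side more were higher in Th1 cells, with 1833 against 1789, and in Th17 cells, with 1686 against 1550. Read-total scaling gave more sites higher in 5 of 5, but it raises every ratio of these comparisons by a log2 of 0.29 to 1.05, which fixes that outcome, so the choice of scaling cannot be told apart from other causes. Restriction to perfect-match reads gave more sites higher in 3 of 5, where reads with mismatches cannot be told apart from fewer reads as a cause. Fewer reads in the perfect-match setting may account for that change. A random draw of as many reads also gave more sites higher in 3 of 5, with 57.6% in Th1, 53.7% in Th17 and 52.9% in iTreg cells. In nTreg cells the share was 30.3% with perfect-match reads and 40.1% in the random draw, so fewer reads alone did not give the lower value there. Whether H3K4me3 as a whole rose or fell in any cell type was not measured, so no direction is given.

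Some sites changed against naive cells in opposite directions in 2 cell types. They were listed because the effects of the same comparison pointed apart. Such sites were a small part of the 16708 sites marked by H3K4me3 and the 5722 marked by H3K27me3 in any cell type. The number that independent changes would give was not computed, so the counts are not read as an excess. The difference itself was not tested, since each cell type had 1 library. For H3K4me3 there were 63 such sites between Th1 and nTreg, 51 between iTreg and nTreg, 46 between Th2 and iTreg, 42 between Th17 and nTreg, and 26 between Th1 and iTreg cells. There were 19 between Th1 and Th2, 18 between Th2 and nTreg, 15 between Th17 and iTreg, 11 between Th2 and Th17, and 10 between Th1 and Th17 cells. For H3K27me3 there were 15 sites between Th2 and iTreg, 9 between Th1 and iTreg, 8 between Th1 and nTreg, 7 between Th2 and nTreg, and 5 between iTreg and nTreg cells. There were 4 between Th17 and iTreg, 4 between Th17 and nTreg, 3 between Th1 and Th17, 3 between Th2 and Th17, and 0 between Th1 and Th2 cells. Under read-total scaling the counts ranged from 15 to 125 for H3K4me3 and from 0 to 79 for H3K27me3. No explanation was tested for these sites.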

How the results depend on the processing

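Perfect-match reads only, autosomes only, background subtraction, thinning of each compared pair and read-total scaling of the counts beyond the comparisons were chosen after seeing the data, and the other alternatives before the data were examined. A count was taken as moved when it differed from the reported count more than 1.5 times. No paired analysis was possible because the labels used here pair no samples. The planned medians of gene lists and the ranks of lists in their own lineage were not run, nor were their alternatives, because gene coordinates were not used. The cause was not tested for any of the changes below unless named.

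All 24 counts of changed sites stayed within that range on autosomes only, with background subtraction and with thinned pairs. Autosomes hold 17805 of the 18317 sites, so leaving out X and Y had little room to move a total. On X itself, 49 of 114 sites were lower for H3K27me3 in iTreg than in naive cells. Background subtraction can remove calls but not add any. The 12 counts of marked sites per cell type and mark, and the 6 counts with both marks, stayed within it with duplicates kept, with the stricter tail, without thinning and with the other windows. With perfect-match reads the 12 counts did so too, but both marks were found at 556 sites in naive, 562 in Th1, 967 in Th2, 732 in Th17, 1023 in iTreg and 369 in nTreg cells.

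Read-total scaling moved all 12 H3K4me3 counts, which follows from the shift it gives every ratio. Higher and lower sites became 5070 and 672 in Th1, 6136 and 949 in Th2, 2677 and 786 in Th17, 6904 and 872 in iTreg and 1583 and 964 in nTreg cells, and 5604 and 1321 between iTreg and nTreg cells. For H3K27me3, 7 of 12 counts moved, to 757 higher and 532 lower in Th17, 400 higher in iTreg, 1128 higher and 189 lower in nTreg cells, and 315 higher and 1247 lower between iTreg and nTreg cells. Of 126 further counts (sites at 4-fold or more, changed in all 5 comparisons, apart in 1 cell type, changed in both marks or in opposite directions, or differing between a pair), 83 moved, 54 up and 29 down.

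Without the requirement of marking, 3 of 12 H3K4me3 counts moved, with 2567 lower in Th1, 4786 in iTreg and 4285 between iTreg and nTreg cells. For H3K27me3, 9 of 12 moved, to 1692 higher in Th1, 1404 higher and 1731 lower in Th2, 1019 higher and 1889 lower in Th17, 486 higher and 1780 lower in iTreg, 3385 lower in nTreg cells, and 2687 higher between iTreg and nTreg cells.

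With duplicates kept, no H3K4me3 count moved and 6 of 12 for H3K27me3 did, to 633 higher in Th1, 521 higher in iTreg, 404 higher and 767 lower in nTreg cells, and 991 higher and 905 lower between iTreg and nTreg cells. Spearman's rho of the marks came closer to 0 in 4 comparisons, at -0.0309 in Th1, -0.1165 in Th2, -0.0938 in Th17 and -0.0438 in iTreg cells, and moved away from it to -0.0475 in nTreg cells. Over all sites rho lay between -0.1717 and -0.0608 in 4 comparisons and reversed to 0.0017 in nTreg cells.

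Windows of 1 kb moved no H3K4me3 count but turned the balance in Th1 cells, to 1833 higher and 1789 lower, and in Th17 cells, to 1686 and 1550. Windows of 5 kb moved 3 H3K27me3 counts, to 669 higher and 517 lower in Th1 and 346 lower in iTreg cells. Perfect-match reads moved 2 H3K27me3 counts, to 247 higher in Th1 and 374 higher in Th2 cells, and 5 for H3K4me3, to 1099 lower in Th1, 1304 in Th2, 1615 in iTreg cells and 1217 between iTreg and nTreg cells, and 430 higher in nTreg cells.

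The length covered by H3K4me3 islands stayed within 1.5 times in each alternative. That of H3K27me3 islands became 119.6 Mb in naive, 69.5 in Th1, 91.2 in Th2, 85.9 in Th17, 112.3 in iTreg and 185.9 in nTreg cells with duplicates kept. With the stricter tail it was 28.4 Mb in naive, 16.2 in Th1, 23.2 in Th2, 26.2 in Th17, 32.0 in iTreg and 41.1 in nTreg cells. Without thinning it was 61.7 Mb in Th1, 87.5 in Th2 and 75.2 in Th17 cells, where more reads allow more bins to pass. In simulated data 48% to 60% of 2-fold changes were called, which the required ratio of 2 limits at any depth, and 90% to 98% of 3-fold changes.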
